A study of Mus musculus with 6 samples.

How the data were processed

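The series holds mouse embryonic heart nuclei profiled with a 10x Genomics Multiome kit, which reads nuclear RNA and open chromatin from the same nucleus. Per the labels, wild-type CD1 hearts were taken at embryonic day 8.5 (E8.5), E10.5 and E16.5, with 1 library per stage. The 6 GEO samples are the RNA part and the ATAC part of each library. Per the labels' protocols, hearts were dissociated to single cells, nuclei were extracted, and libraries were read on an Illumina NovaSeq. Per the submitters' processing notes and the deposited matrix headers, reads were processed with Cell Ranger ARC 1.0.1 against mm10. The aligner's settings and the rule that called nuclei are not given in the sources used here. The number of embryos per library and their sex are not given in the labels either.

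The values used were the authors' deposited matrices, whose rows are genes, in unique molecular identifiers (UMIs) per the file headers, and peaks, in counts of cut sites. That peak unit was read from the values themselves, because 86.0%, 85.0% and 89.6% of nonzero peak counts were even at E8.5, E10.5 and E16.5. Every matrix column was used. The deposited files listed 7483, 4922 and 6773 barcodes, 32285 genes in each library, and 117392, 123405 and 157449 peaks. Totals were 64475733, 55841182 and 34633377 UMIs, and 123047891, 108695198 and 124524382 peak counts. The median barcode had 6935, 8795 and 3840 UMIs, 3137, 3298 and 1932 genes, and 14046, 17792.5 and 13553 peak counts.

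Nuclei were kept with at least 500 UMIs, 300 genes and 1000 peak counts and a mitochondrial share of UMIs under 20%. Under 500 UMIs were 13, 6 and 252 barcodes, under 1000 peak counts 232, 116 and 240, and at or over the mitochondrial limit 10, 171 and 1194. This left 7231, 4636 and 5169 nuclei. Doublets were scored by comparing each nucleus with simulated sums of pairs, as Scrublet does, in code written for this work. An automatic threshold called 2, 248 and 0 nuclei, so the 6% of nuclei with the highest scores in each library were left out instead, 434, 278 and 310 nuclei. That rule was chosen after the scores had been seen. Kept were 6797, 4358 and 4859 nuclei, with medians of 6760, 8467 and 3327 UMIs, 14006, 17807.5 and 14626 peak counts, and mitochondrial shares of 4.58%, 10.6% and 9.47%.

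Each library was clustered on its own RNA with Scanpy, on 3000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, giving 29, 21 and 28 clusters. All genes of the 18 marker lists and the 23 gene lists were kept out of the variable genes. A cluster took the class with the highest share of its markers raised. A marker was raised at 2 times the median cluster or more, with at least 10 UMIs and 25% of the highest cluster. The class had to have at least 3 raised markers and 33.3% of its list, lead by 0.1, and hold the most markers among the cluster's 10 leading genes. A cluster with few UMIs needed 5 of its own markers among those 10. These naming thresholds were set after cluster marker tables had been seen and before any ratio between stages was made. They left 40.4%, 15.4% and 30.4% of kept nuclei unnamed. Classes carry the ending -like because markers alone named them. The lists themselves were fixed from general knowledge before the data were examined.

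Raw UMIs were summed over the nuclei of a class and scaled to the total UMIs of that class as CPM. Classes with at least 100 nuclei in both libraries were compared, which gave cardiomyocyte-like, endothelial-like, mesenchymal-like and epicardial-like nuclei. E16.5 was compared with E8.5, then E10.5 with E8.5 and E16.5 with E10.5. With 1 library per stage no test between stages was run and no standard error was made from nuclei. Intervals are 95% exact Poisson intervals for sums and ratios and exact binomial intervals for shares, covering counting error only. A gene with 0 UMIs in one library is given as a bound against a floor of 3 UMIs. A list member with at least 50 UMIs in the 2 sums was counted as higher or lower at a ratio of 2, a rule of size, not a test.

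Individual genes were named by a fixed rule. It asked for 100 UMIs in the 2 sums, 50 CPM in the higher library, and a class level of at least 0.5 times that of all other nuclei. The lower Poisson bound of the higher level had to be at least 2 times the upper bound of the lower level, and the 12 genes with the largest bound ratio in each direction were taken. Mitochondrial genes, Xist, Tsix, chromosome Y genes, haemoglobin genes and numbered gene models were left out. From each list the 2 members with the largest and the 2 with the smallest ratios were taken as well.

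For each list the median log2 ratio was set beside 10000 random lists of the same size matched on expression. The resulting percentile describes these libraries, genes not being replicates. Lists covered sarcomere and contractile genes, calcium handling and ion channels, fatty acid oxidation, glycolysis, the nuclear-encoded respiratory chain, mitosis, DNA replication, atrial genes, ventricular and trabecular genes, and cardiac transcription factors. They also covered heart field progenitors, heterochronic and oncofetal genes, imprinted genes, extracellular matrix, arterial, venous and lymphatic, endocardial, and coronary and capillary endothelium. The remaining lists were cushion and endothelial to mesenchymal transition, Hox genes, locus-associated noncoding RNA, haemoglobin, and immediate early and stress genes. The report gives list medians less the median of all measured genes.

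Peaks had been listed per library, so sharing was defined as an overlap of at least 50% of each peak. Shared peaks can differ in width by up to 2-fold, which can raise a peak ratio between stages by as much. A gene start was the interval spanned by the gene's start sites in the deposited feature list. Peaks within 1 kb of it were promoter-proximal and all others distal, and distal peaks were linked to every start within 100 kb. Poisson intervals of peak ratios use 0.5 times the counts, 1 per fragment. For 38 loci the distal peak with the largest ratio by its bound was taken, so it is the largest of many. Gene biotypes came from the RefSeq table of GRCm38.p6, the assembly called mm10, which matched 26696 of 32285 genes (82.7%). Noncoding genes were set beside a peak when their start lay within 500 bp of it and it was over 1 kb from every protein-coding start. Such peaks are called distal in that part only, since by the rule above they are promoter-proximal to the noncoding gene.

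Alternatives tried were Leiden resolutions of 0.5 and 2, doublets kept, listed genes kept in clustering, clusters made on peak counts alone, and the 3 libraries clustered together. A stricter filter asked for 1000 UMIs, 2000 peak counts and a mitochondrial share under 5%, and another run used no mitochondrial limit with doublets kept. Ratios were remade with median-of-ratios scaling, without mitochondrial, haemoglobin and Malat1 UMIs, with each nucleus given the same weight, with nuclei thinned to 1000 UMIs, and with no minimum count. Peak results were remade with an overlap of 1 base, the 50% of peaks with the most counts, a promoter distance of 2 kb, a distal window of 50 kb, the nearest start only, scaling on proximal peaks, and a noncoding distance of 5 kb.

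The gene ratios were tested on simulated data, in which 50 genes each were set to 2-fold, 0.5-fold, 4-fold and 0.25-fold. Both sums were drawn as Poisson counts around 1 shared mean, so the simulation held counting error only. It checks the code and gives no error rate for differences between preparations. Past the 2-fold bound were 0, 3, 50 and 50 of the altered genes, and 0 of 10496 unaltered genes. Of 200 unaltered random lists, 3.5% had a percentile under 2.5 or over 97.5. A list set to 4-fold came back with a median log2 ratio of 1.93 and a percentile of 100. Nearest starts and overlaps were checked against brute force on 300 cases each, with 0 differing.

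Software was Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Scanpy 1.11.5, AnnData 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and Matplotlib 3.10.9, with random seed 1.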

Results

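Nuclei from mouse embryonic hearts were compared across 3 stages, E8.5, when the heart tube forms and loops, E10.5, when chambers grow, and E16.5, when the fetal heart has its chambers, valves and coronary vessels. RNA and open chromatin came from the same nuclei, in 1 library per stage. After filtering, 6797, 4358 and 4859 nuclei were kept at E8.5, E10.5 and E16.5, with medians of 6760, 8467 and 3327 UMIs and 14006, 17807.5 and 14626 peak counts. The labels give 10000 nuclei as the input of each library, beside 7483, 4922 and 6773 listed barcodes. Stage is the same thing as library here, so differences between stages include any difference between preparations, and all intervals cover counting error only.

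Cardiomyocyte-like nuclei made up the largest named class at E10.5 and E16.5. Their share was 12.8% (11.97 to 13.57) at E8.5, 40.5% (39.0 to 42.0) at E10.5 and 21.9% (20.7 to 23.0) at E16.5. With no limit on mitochondrial RNA and doublets kept, the E16.5 share was 36.0%, and the unnamed share was 18.1%. Endothelial-like nuclei, which include the endocardium, were 6.72%, 24.7% and 17.3%. Epicardial-like nuclei, named by markers of the heart's outer layer, were 2.94%, 14.1% and 3.38%. The E8.5 class had no UMIs of the listed mesothelial markers Msln and Muc16. At E8.5, resolution 0.5, clusters made on peak counts and libraries clustered together gave no such class. Mesenchymal-like nuclei were 11.3%, 0.826% and 16.7%, but these shares depended on the clustering. At E8.5 they were 3.28% at resolution 0.5, 4.08% at resolution 2 and 1.34% on peak counts, and no cluster was so named with the libraries together, which gave 12.1% at E10.5. Mural-like nuclei, carrying markers of smooth muscle and pericytes, were 7.37% (6.65 to 8.14) at E16.5, with an upper limit of 0.0846% at E10.5 under the naming rule. A further 3.03% of E10.5 nuclei lay in an unnamed cluster led by mural markers, and clusters made on peak counts gave mural-like shares of 3.49% at E10.5 and 1.67% at E16.5. The E8.5 library also held nuclei with markers of other tissues, among them unnamed clusters led by endodermal (3.58%) and extraembryonic (3.05%) markers. Surface epithelial-like nuclei were 13.5% there, neural crest or glial-like 3.99%, pharyngeal or second heart field mesoderm-like 2.69% and hepatic-like 2.57%. Neural crest or glial-like nuclei were 12.1% at resolution 0.5, and hepatic-like nuclei were 4.02% with listed genes kept and were not named on peak counts. Erythroid-like nuclei were 3.15% at E8.5 and 1.35% at E10.5, and no cluster was so named at E16.5. The stricter filter gave erythroid-like shares of 1.09% and 25.6%, and none were named with the libraries clustered together. Myeloid-like nuclei, the resident macrophage lineage, were 0.390% at E10.5 and 1.67% at E16.5, where resolution 0.5 gave 2.78% and kept doublets 2.82%, and none were named at E10.5 on peak counts. Unnamed clusters held 40.4%, 15.4% and 30.4%. Those led by cardiomyocyte markers were 5.36% of nuclei at E8.5, 0% at E10.5 and 16.2% at E16.5, and those led by mesenchymal markers were 18.6%, 10.9% and 7.74%.

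**Figure D1:**
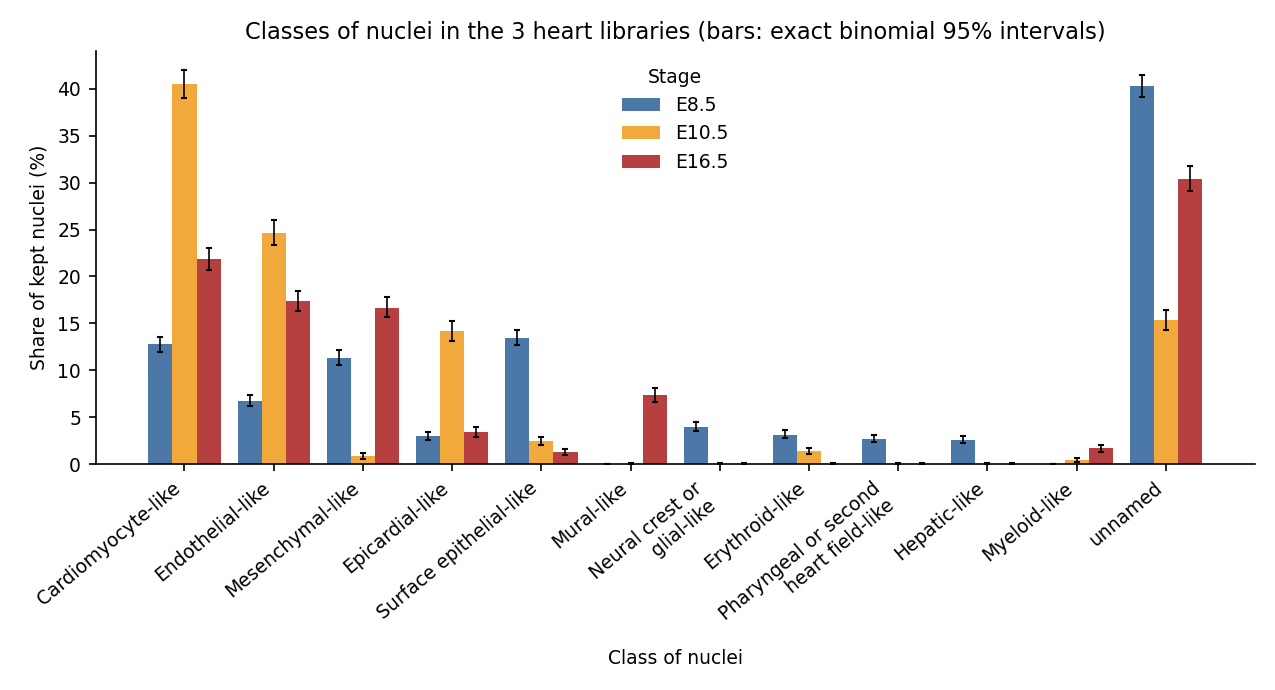
Bars show the share of kept nuclei (percent) in each named class at E8.5, E10.5 and E16.5, with exact binomial 95% intervals. Cardiomyocyte-like nuclei were 12.8%, 40.5% and 21.9%.

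Between E8.5 and E16.5 cardiomyocyte-like nuclei differed in RNA of genes for metabolism, calcium handling and the cell cycle. The lists for fatty acid oxidation, the respiratory chain and calcium handling had higher medians at E16.5, with many members under 2-fold. The cell cycle, heart field and heterochronic lists had lower medians. The median of all 12233 measured genes was -0.25 in log2, and list medians are given relative to such a median throughout, while single genes are given as plain ratios.

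Fatty acid oxidation was the list with the highest median in these nuclei, 1.71 (percentile 100 among random lists), with 18 of 25 members at least 2-fold higher and 0 lower. Ppara, a nuclear receptor that switches on fat-burning genes, was at 35.0 CPM at E16.5 and 0.770 CPM at E8.5, 45.5-fold. Cpt1a, which admits long-chain fatty acids to mitochondria, was 33.8-fold higher. Pdk4, a kinase that shuts glucose carbon out of mitochondria, was 17.7-fold higher. The fatty acid transporter Cd36 was 9.85-fold higher, the dehydrogenase Acadl 9.07-fold and the fatty acid binder Fabp3 5.85-fold. Ppargc1a, a coactivator of mitochondrial genes, was at 84.2, 141 and 328 CPM from E8.5 to E16.5. Esrrg, an orphan nuclear receptor of oxidative muscle, was at 371, 263 and 378 CPM. The respiratory chain list had a median of 1.11 (percentile 99.99), with 9 of 22 members higher and 0 lower. Cox8b, a muscle subunit of cytochrome oxidase, was 86.1-fold higher, and the mitochondrial creatine kinase Ckmt2 12.2-fold. Mitochondrially encoded RNA, a sign of both muscle and nuclear preparation quality, was at 63853, 117780 and 159602 CPM in these nuclei and at 53425, 110926 and 89809 CPM in all others.

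Glycolysis as a list had a median of -0.17 (percentile 28.9), with 2 of 18 members higher and 6 lower, and 0.29 at E10.5 against E8.5 (percentile 83.8). The lower members included the glucose entry and lactate exit steps, beside the enzymes Pgam1 and Eno1. The hexokinase Hk2 was at 617, 169 and 42.7 CPM and 14.4-fold lower at E16.5 than at E8.5. The glucose transporter Slc2a3 was 9.72-fold lower, the lactate exporter Slc16a3 7.65-fold and the glucose transporter Slc2a1 5.797-fold. Pfkm, the muscle phosphofructokinase, was 3.77-fold higher.

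The sarcomere and contractile list had a median of 1.12 (percentile 100), with 15 of 33 members higher and 3 lower. Myom2, an M-band protein of fast and mature muscle, was at 79.6 CPM (73.6 to 86.1) at E16.5 and 0.0855 CPM (0.00217 to 0.477) at E8.5. Myoz2, a Z-disc binder of calcineurin, was 84.8-fold higher. Tnni3, the adult cardiac troponin I, was at 222, 807 and 1453 CPM. Csrp3, a Z-disc LIM protein, was at 373, 926 and 1534 CPM. The 3 lower members were smooth and skeletal muscle genes of the early heart tube, but not every such gene of the list was among them. The skeletal troponins Tnni1 and Tnnt1 were at 957, 1529 and 1746 CPM and at 76.8, 284 and 160 CPM. The smooth muscle calponin Cnn1 was at 183, 222 and 112 CPM. Tagln, an actin-binding protein of smooth muscle, was 7.005-fold lower, the smooth muscle actin Acta2 5.68-fold and the skeletal actin Acta1 4.33-fold. Outside the list, Ckm, the muscle creatine kinase, was at 1048 CPM (1025 to 1070) and 0.941 CPM (0.470 to 1.68), 1114-fold higher. Mb, the oxygen store myoglobin, was at 236 CPM and 2.99 CPM, and Nrap, which anchors growing myofibrils, at 364 CPM and 6.07 CPM. Lmod1, a smooth muscle leiomodin, was 41.9-fold lower.

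Calcium handling and ion channel genes had a median of 0.86 (percentile 100), with 12 of 29 members higher and 2 lower. Sln, which restrains the calcium pump in atria, was at 400 CPM (386 to 414) at E16.5 and 0.0855 CPM (0.00217 to 0.477) at E8.5. Casq2, the calcium store of the sarcoplasmic reticulum, was at 541 CPM and 2.91 CPM, 186-fold. Pln, another brake on the pump, was 11.0-fold higher, and the T-type calcium channel Cacna1g 28.3-fold. The pump itself, Atp2a2, was at 1570, 1349 and 1828 CPM, and the release channel Ryr2 at 2902, 1606 and 2635 CPM. The potassium channels Kcnj3 and Kcnq1 were 12.3-fold and 10.5-fold higher. The L-type channel Cacna1d was 2.78-fold lower. Fgf12, an intracellular modulator of sodium channels, was 149-fold higher, at 587 CPM and 3.93 CPM.

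Outside the lists, the synaptic adhesion gene Lrrc4c was 1109-fold higher, the clathrin coat gene Snap91 62.5-fold and the axon guidance gene Nav3 55.5-fold, though Nav3 was as high in the other E16.5 nuclei (323 CPM). Ptgds, a prostaglandin synthase, was at 55.6 CPM (50.5 to 61.0) at E16.5 and 0.0855 CPM (0.00217 to 0.477) at E8.5.

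Cell cycle lists were lower almost throughout. Mitosis had a median of -1.16 (percentile 0), with 23 of 24 members lower, and DNA replication -1.52 (percentile 0), with 21 of 24 lower. Top2a, the topoisomerase of dividing cells, was at 616, 290 and 147 CPM, and the proliferation marker Mki67 at 243, 167 and 91.5 CPM. Kif23, needed to split daughter cells, was 3.74-fold lower. Uhrf1, which copies DNA methylation, was 5.89-fold lower and the replicative helicase subunit Mcm7 4.601-fold. In nuclei thinned to 1000 UMIs, 13 DNA replication genes were at least 2-fold lower, but fewer genes of any kind were measured there, 5988 against 12233.

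Heterochronic and oncofetal genes, which time development, had the lowest list median, -3.10 (percentile 0), with 9 of 10 members lower. Lin28a, the blocker of let-7 microRNAs, was at 0 CPM at E16.5 and 56.5 CPM (52.2 to 60.9) at E8.5, at least 149-fold. Trim71, a let-7 target, was at 0.378 CPM (0.0780 to 1.10) and 102 CPM (96.7 to 108). The chromatin protein Hmga2 was 56.0-fold lower. The other E8.5 nuclei held as much of them, with 71.5 CPM of Lin28a, 158 CPM of Trim71 and 610 CPM of Hmga2. Prtg, a receptor of early mesoderm and neural tissue, was at 14.9 CPM and 716 CPM, with 757 CPM in the other E8.5 nuclei.

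Heart field progenitor genes had a median of -2.19 (percentile 0), with 8 of 12 members lower. Markers of pharyngeal or second heart field mesoderm were lower in other nuclei too. They summed to 171 CPM at E8.5 and 95.5 CPM at E10.5 in cardiomyocyte-like nuclei, and to 377 and 89.1 CPM in all others. Tdgf1, a Nodal co-receptor of the outflow tract, was at 0.126 CPM (0.00319 to 0.702) at E16.5 and 75.0 CPM (70.1 to 80.1) at E8.5. Wnt2, from the inflow region, was 103-fold lower and the second heart field signal Fgf10 12.7-fold. Fgf8, another signal of that field, had no UMIs at E16.5 and was at least 45.7-fold lower. Cardiac transcription factors as a list had a median of 0.06 (percentile 63.7), with 2 of 26 members higher and 4 lower. Mef2a was 3.42-fold higher and Mef2c, its earlier relative, 3.48-fold lower. Gata5, an endocardial and early myocardial factor, was 8.07-fold lower. Nkx2-5, the core cardiac factor, was at 208, 206 and 157 CPM, Gata4 at 268, 183 and 256 CPM and Tbx20 at 475, 285 and 438 CPM.

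The lists of both chambers had higher medians. The atrial list had a median of 0.74 (percentile 99.6), with 6 of 15 members higher and 0 lower, and the ventricular and trabecular list 0.81 (percentile 99.9), with 7 of 18 higher and 4 lower. Nppa, a natriuretic peptide of atria and trabeculae, was at 698, 1355 and 3046 CPM. The potassium channel subunit Kcne1 was 18.6-fold higher. Mpped2, a phosphodiesterase of the ventricular list, was 8.38-fold lower, Hand1, a factor of the early left ventricle, 7.83-fold and the growth-promoting transcription factor Mycn 6.37-fold. The myosin chains Myh7 and Myh6 were 2.65-fold and 1.64-fold higher.

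Matrix genes in these nuclei pointed both ways. The extracellular matrix list had a median of 0.61 (percentile 99.8), with 9 of 28 members higher and 7 lower, and thinning nuclei to 1000 UMIs gave 0.10 (percentile 72.9). Eln, the elastin of vessel walls, was 161-fold higher and the proteoglycan Dcn 13.5-fold, both also fibroblast genes. Has2, which makes the hyaluronan of cardiac jelly, was at 0.504 CPM and 99.5 CPM, 197-fold lower, its linker Hapln1 9.89-fold lower and the proteoglycan Vcan 7.90-fold. Col2a1, a cartilage-type collagen, was 98.6-fold lower. The cushion list had a median of -0.29 (percentile 13.8), with 2 of 17 members higher and 6 lower.

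Endothelial genes counted in cardiomyocyte-like nuclei may be RNA from neighbours or from the nuclei themselves, which was not tested. Cd36, for one, is on both the coronary and the fatty acid oxidation list. Endothelial markers summed to 148, 162 and 262 CPM in these nuclei against 1231, 3416 and 3973 CPM in all others. The coronary and capillary list had a median of 0.70 (percentile 98.1), with Fabp4 at 106 CPM (99.4 to 114) at E16.5 and 0.257 CPM (0.0529 to 0.750) at E8.5. The endocardial list had -1.63 (percentile 0), with 6 of 11 lower, among them the trabecular growth signal Nrg1, 14.0-fold. Arterial genes had -0.07 (percentile 39.2) and venous and lymphatic genes 0.26 (percentile 79.2). The guidance receptor Nrp2 was 18.1-fold lower and the Notch ligand Jag1 7.36-fold.

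Imprinted genes had a median of -0.75 (percentile 0.06), with 10 of 20 lower and 0 higher. The growth inhibitor Cdkn1c was 5.73-fold lower and the retrotransposon-derived Peg10 11.3-fold. Of the Hox list 1 member, Hoxb2, was measured, and it was lower. Noncoding RNA genes at cardiac loci had -0.04 (percentile 46.9), with the microRNA host Mir100hg 14.4-fold higher and Mhrt, antisense to Myh7, 5.90-fold lower. Haemoglobin genes had -1.53 (percentile 0.05), but members pointed both ways, and 5 other settings turned that median to higher. Embryonic Hba-x was at 108, 46.6 and 1.39 CPM and Hbb-bs at 2.14, 4.57 and 102 CPM. Immediate early and stress genes, which respond to dissociation, had 0.86 (percentile 99.7), with Egr1 at 226, 947 and 575 CPM.

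**Figure D2:**
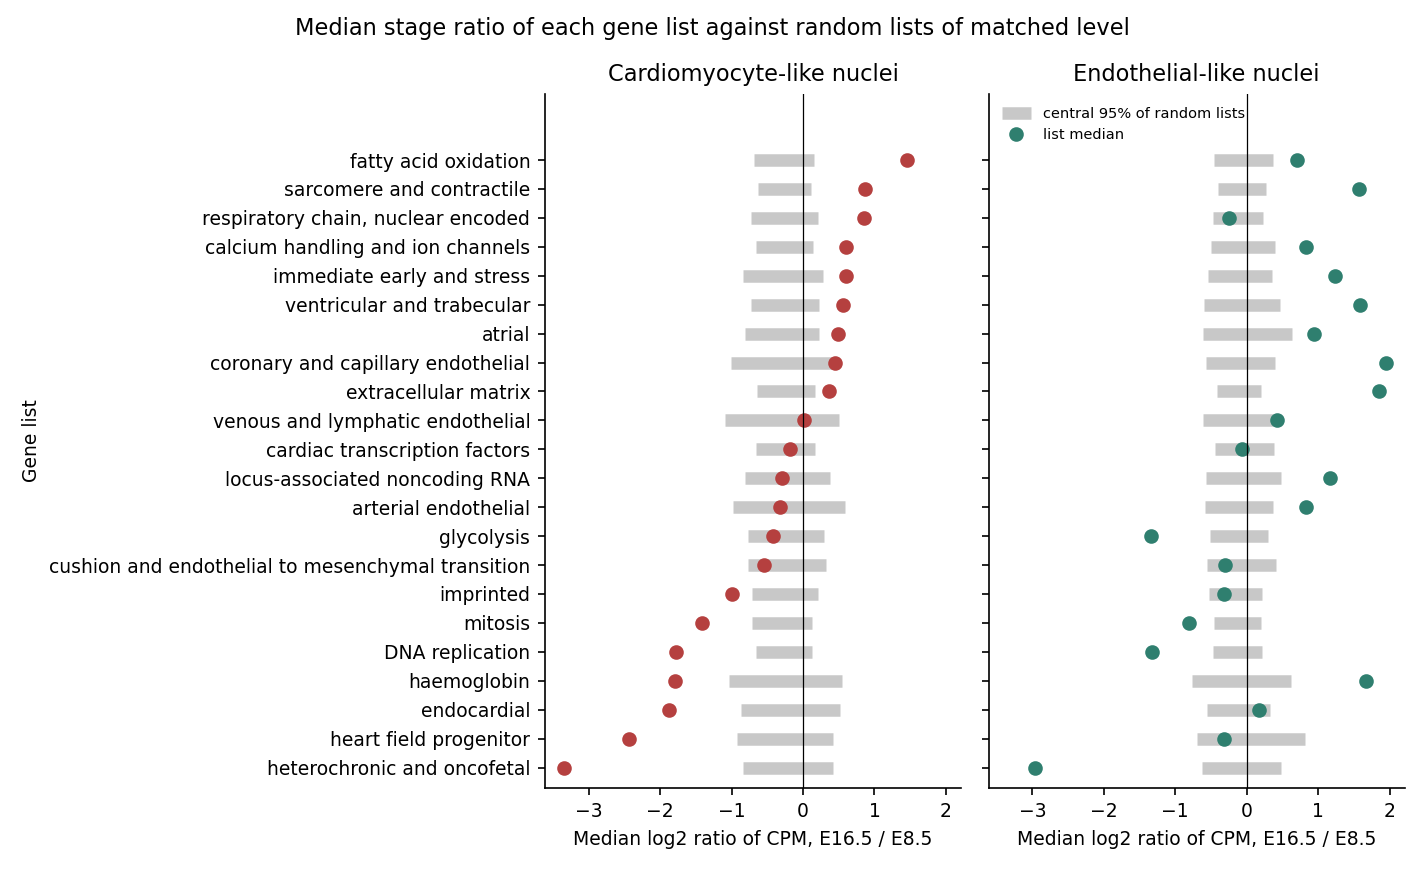
Points show the median log2 ratio of each gene list, E16.5 over E8.5, before setting against all genes, and grey bars the central 95% of 10000 random lists, for cardiomyocyte-like and endothelial-like nuclei. Fatty acid oxidation was at 1.46 and heterochronic genes at -3.35 in cardiomyocyte-like nuclei.

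The E10.5 library divides these differences, with all-gene medians of -0.19 against E8.5 and -0.05 for E16.5 against E10.5. Against E8.5 the cardiomyocyte-like nuclei of E10.5 already had lower heterochronic genes (median -1.33, 7 of 10 lower) and lower heart field genes (-1.07, 8 of 15 lower). Lin28a was 198-fold lower and Tdgf1 167-fold. Fatty acid oxidation genes had a median of 0.95 (percentile 100), with 9 of 24 higher, and respiratory chain genes 0.97. Ventricular genes had 0.89 and atrial genes 0.80. Among single genes Shox2, a factor of the sinus node, was at 71.1 CPM and 2.82 CPM, the netrin receptor Dcc at 99.6 CPM and 2.57 CPM and the elongation factor Eef1a2 at 73.6 CPM and 5.73 CPM. Mitosis genes had only -0.39, with 1 of 24 lower, and DNA replication genes -0.50, with 3 of 24 lower. Immediate early genes were higher here as well, 1.16.

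From E10.5 to E16.5 the cell cycle lists were lower by more, -0.82 for mitosis with 8 of 24 members lower and -0.999 for DNA replication with 15 lower. Fatty acid oxidation genes had 0.79 (percentile 100), with 11 of 25 higher, and calcium handling genes 0.63, with 9 of 30 higher. Respiratory chain genes had 0.15 (percentile 89.4) and ventricular genes -0.15. Glycolysis genes had -0.45 (percentile 1.90), with 5 of 18 lower. Ckm was 143-fold higher, Sln 58.6-fold and Casq2 22.4-fold. Nr3c2, the mineralocorticoid receptor, was 15.04-fold higher. The ribosomal protein genes Rps28, Rpl38 and Rps29 were 7.06-fold, 6.77-fold and 5.98-fold lower, as they were in all other nuclei, where Rps28 was at 267 CPM and 1336 CPM.

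**Figure D3:**
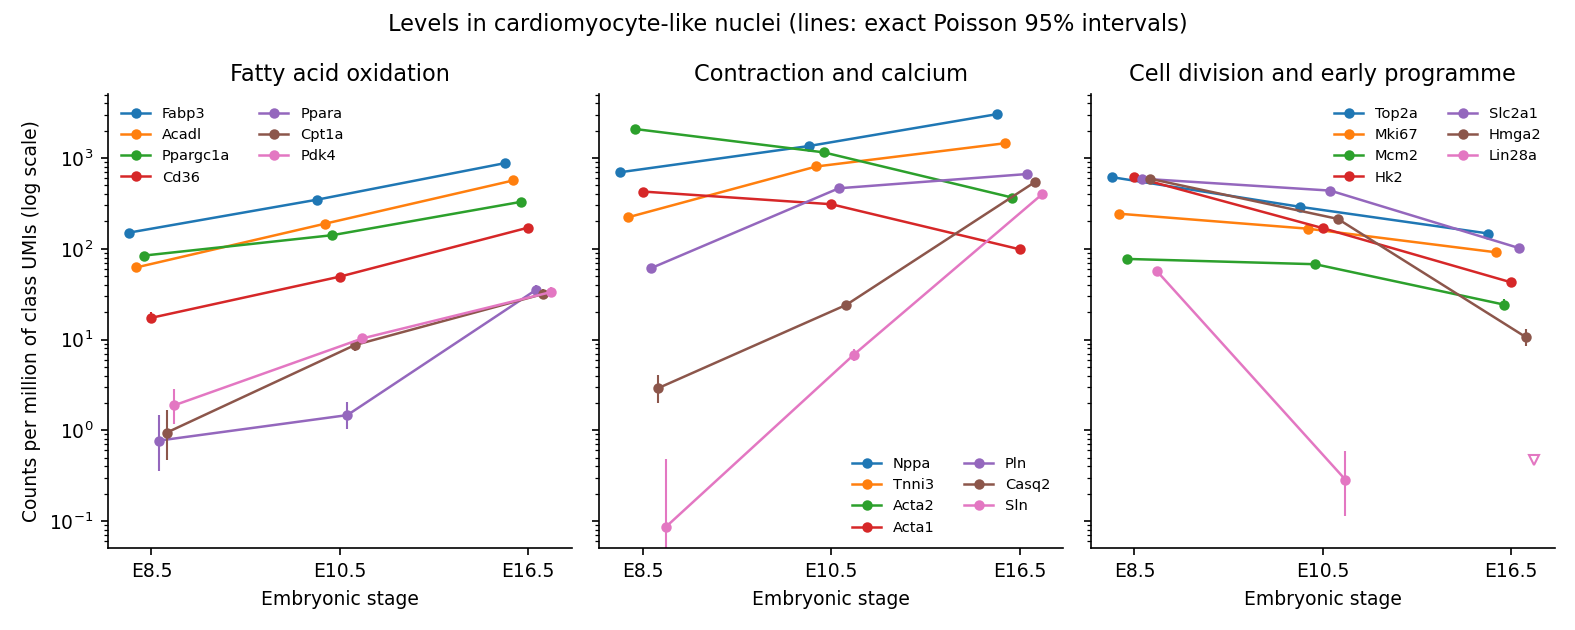
Lines show the level of single genes (CPM, log scale) in cardiomyocyte-like nuclei at E8.5, E10.5 and E16.5, in 3 panels for fatty acid use, contraction and calcium, and cell cycle, glucose use and timing. Fabp3 was at 151, 348 and 881 CPM and Top2a at 616, 290 and 147 CPM; the open triangle marks the upper bound of a level of 0.

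Endothelial-like nuclei at E16.5 had higher medians than at E8.5 for the coronary and capillary, extracellular matrix and arterial lists. The glycolysis, cell cycle and heterochronic lists had lower medians. The E16.5 class includes a cluster of 319 nuclei led by Btnl9 and 1 of 39 nuclei led by Ccl21a, Mmrn1 and Reln. The E8.5 class carried 922 CPM of lymphoid or mast markers, against 129 CPM in all other E8.5 nuclei. That library also held nuclei of other tissues. The endothelial-like class may therefore differ in kind between stages, and its ratios need not be changes within 1 cell type.

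The coronary and capillary list had a median of 2.03 (percentile 100), with 8 of 13 members higher and 2 lower, relative to an all-gene median of -0.08. Fabp4, a fatty acid binder of capillaries, was at 1092 CPM (1062 to 1123) at E16.5 with no UMIs at E8.5, at least 1872-fold. Gpihbp1, which holds lipoprotein lipase in capillaries, was 63.2-fold higher and the cell cycle regulator Rgcc 59.1-fold. The lipase Mgll was 216-fold higher, the caveolar gene Cav1 123-fold, and Cd36 4.37-fold. Meox2, a homeobox gene of capillaries that take up fat, was at 56.0 CPM (49.3 to 63.4) and 0.194 CPM (0.00492 to 1.08). Btnl9, a capillary surface gene, was at 102 CPM (93.2 to 112) and 0.194 CPM (0.00492 to 1.08). The carbonic anhydrase Car4 was 12.2-fold lower. Fatty acid oxidation genes had a median of 0.79 (percentile 99.9), with 10 of 22 higher, and respiratory chain genes -0.16 (percentile 26.2).

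Arterial genes had a median of 0.92 (percentile 99.95), with 5 of 13 higher and 2 lower. Jag2 and Jag1, Notch ligands of arteries, were 6.87-fold and 4.09-fold higher, while the Notch target Hey1 was 4.95-fold lower and the ligand Dll4 2.13-fold. Hes1, another Notch target, was 10.9-fold lower. Venous and lymphatic genes had 0.51 (percentile 98.4), with 4 of 10 higher and 1 lower. Ccl21a, the chemokine of lymphatic vessels, was at 181 CPM with no UMIs at E8.5, at least 311-fold. Reln, made by lymphatic endothelium, was 8.98-fold higher and Prox1, the lymphatic and valve factor, 3.69-fold, while the hyaluronan receptor Lyve1 was 3.68-fold lower. Endocardial genes had 0.26 (percentile 91.7), with 4 of 14 higher and 2 lower. Cdh11, a cadherin of valve endocardium, was 10.3-fold higher and Hapln1 10.6-fold lower.

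Extracellular matrix genes had a median of 1.93 (percentile 100), with 17 of 29 higher and 3 lower. Eln was at 1409 CPM (1374 to 1444) and 0.389 CPM (0.0471 to 1.41), with 1312 CPM in all other E16.5 nuclei. Fbln5, an organiser of elastic fibres, was at 294 CPM (278 to 310) and 0.194 CPM (0.00492 to 1.08). Fbln2, a fibulin of valves, was 56.3-fold higher and the periostin gene Postn 12.2-fold, while Has2 was 10.2-fold lower. Mgp, an inhibitor of calcification, was at 247 CPM here and 402 CPM in other E16.5 nuclei. Mesenchymal markers summed to 1158, 3103 and 3410 CPM in endothelial-like nuclei over the 3 stages. The cushion list had -0.23 (percentile 17.9), with 4 of 14 higher and 4 lower.

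Glycolysis genes had a median of -1.26 (percentile 0), with 9 of 17 lower and 1 higher. Hk2 was at 227, 82.5 and 4.70 CPM, 48.2-fold lower. Slc2a3 was 26.1-fold lower and Slc2a1 7.04-fold, while the hexokinase Hk1 was 2.51-fold higher. Mitosis genes had -0.73 (percentile 0), with 9 of 24 lower, and DNA replication genes -1.25 (percentile 0), with 17 of 24 lower. Heterochronic genes had -2.88 (percentile 0), with 8 of 10 lower, including Hmga2 15.5-fold and Lin28b 11.7-fold. Stab2, a scavenger receptor of sinusoidal vessels, was at 1.34 CPM and 197 CPM, 147-fold lower. Tnfaip2, a gene induced by tumour necrosis factor, was 13.6-fold lower and Itga2b, an integrin of blood-forming endothelium and megakaryocytes, 13.1-fold. Megakaryocyte markers summed to 61.7 CPM at E8.5 and 9.63 CPM at E16.5 in these nuclei, and myeloid markers to 330 and 120 CPM.

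Imprinted genes had -0.23 (percentile 20.3), with the G protein gene Gnas 3.15-fold higher and the imprinted gene Zdbf2 4.35-fold lower. Cardiac transcription factors had 0.01 (percentile 47.5), although Prdm16, a factor of arterial endothelium, was 13.5-fold higher. Heart field genes had -0.24 (percentile 19.4) and Hox genes 0.29 (percentile 65.8). Noncoding RNA genes had 1.24 (percentile 99.97), with Hand2os1, the antisense neighbour of Hand2, 5.46-fold higher. Haemoglobin genes had 1.75 (percentile 99.97), with Hbb-bs, a globin gene of red cells, at 2.92, 5.57 and 305 CPM, but thinning to 1000 UMIs gave a median of 0.04 (percentile 63.1). Immediate early genes had 1.32 (percentile 100), with Fos 5.03-fold higher.

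Muscle lists were also higher in endothelial-like nuclei, sarcomere 1.66 (percentile 100, 18 of 29 higher), ventricular 1.67 (percentile 100), atrial 1.03 (percentile 99.6) and calcium handling 0.92 (percentile 99.9). Tnni3 was at 12.3, 70.2 and 132 CPM and Myl2, the ventricular light chain, at 117, 538 and 601 CPM. Cardiomyocyte markers summed to 1386, 2421 and 3221 CPM in endothelial-like nuclei and to 3223, 3655 and 3429 CPM in epicardial-like nuclei, a class that is not muscle.

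Against E8.5, endothelial-like nuclei at E10.5 had lower medians for the capillary and venous lists and higher medians for the endocardial and matrix lists. Whether the 3 libraries sampled the same vessels was not tested. Relative to an all-gene median of -0.17, the coronary and capillary list had -1.97 against E8.5 (percentile 0), with 6 of 8 lower. At E16.5 against E10.5, where the all-gene median was 0.07, it had 5.13 (percentile 100), with 9 of 12 higher. Cldn5, the tight junction claudin, was at 211, 16.5 and 317 CPM and Cd36 at 98.4, 9.58 and 430 CPM. Venous and lymphatic genes had -0.85 at E10.5 against E8.5 and 0.97 at E16.5 against E10.5. Endocardial genes had 0.61 at E10.5 against E8.5 (percentile 100), with 4 of 14 higher, and Cdh11 was at 66.5, 484 and 686 CPM. Matrix genes had 0.66 at E10.5 against E8.5. Against E8.5 the chemokine Ccl2 was at 84.0 CPM and 3.11 CPM and the adhesion gene Sele at 83.0 CPM and 5.06 CPM, beside immediate early genes at 0.92. Between E10.5 and E16.5 Gpihbp1 was 273-fold higher and Sparcl1, a matricellular gene, 48.8-fold, while Cdkn1c was 7.34-fold lower.

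Mesenchymal-like nuclei were compared between E8.5 and E16.5 only, and the class differs in kind, with an all-gene median of -0.14. At E8.5 its nuclei carried 992 CPM of epicardial markers and 581 CPM of endodermal markers, against 163 and 5.47 CPM at E16.5, while mural markers were at 217 and 2007 CPM. Extracellular matrix genes had a median of 1.83 (percentile 100), with 20 of 30 higher and 0 lower. Dpt, a dermatopontin of fibroblasts, was at least 523-fold higher and Mgp at least 1097-fold. Eln was 450-fold higher, Nfix, a factor of fetal maturation, 242-fold and Col15a1, a basement membrane collagen, 203-fold. Acan, the aggrecan of valve and cartilage, was at least 110-fold higher. Hox genes had -3.28 (percentile 0.0200), with 5 of 5 lower, such as Hoxb4 at 4.45 CPM and 47.6 CPM. Krt8, a keratin of simple epithelia, was 276-fold lower and Hsd11b2, a glucocorticoid-inactivating enzyme, at least 208-fold. Mab21l2, a gene of early body wall mesenchyme, was at least 94.5-fold lower. Mitosis genes had -1.20, with 22 of 24 lower. Glycolysis genes had -1.24, with 11 of 17 lower, and Slc2a1 was at 27.0 CPM and 331 CPM. Cushion genes had 0.75 (percentile 99.6), with 9 of 19 higher, and immediate early genes 1.304.

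Epicardial-like nuclei had more cell cycle RNA at E8.5 and E10.5 and more matrix RNA at E16.5, with an all-gene median of -0.27 for E16.5 against E8.5. This class too may differ in kind between stages, so its ratios need not be changes within 1 cell type. At E8.5 it carried 1221 CPM of epicardial markers, against 992 CPM in E8.5 mesenchymal-like nuclei. The extracellular matrix list had a median of 2.52 at E16.5 against E8.5 (percentile 100), with 21 of 28 higher and 4 lower. Col1a1, the main fibrillar collagen, was at 6681 CPM and 211 CPM, and Col3a1 at 7564 CPM and 196 CPM, while mesenchymal markers summed to 2588, 4694 and 25364 CPM over the 3 stages. Msln and its binding partner Muc16, of serosal surfaces, were at least 368-fold and 328-fold higher, with no UMIs at E8.5, though both are on the marker list of the class. Aldh1a2, which makes retinoic acid, was at 335 CPM (302 to 370) and 0.633 CPM (0.0160 to 3.53). Mitosis genes had -1.54 against E8.5 and -1.71 against E10.5 (percentile 0), with 24 of 24 lower in each, but 0.23 at E10.5 against E8.5. Itga4, an integrin needed for epicardial attachment, was at 0.875 CPM (0.0222 to 4.88) and 762 CPM (719 to 806). Sfrp5, a Wnt inhibitor of the inflow region, was 65.3-fold lower and Robo2, the Slit receptor, 22.8-fold. At E10.5 against E8.5 Krt7, a keratin of mesothelium, was 30.6-fold higher and Fgf10 34.2-fold lower, with matrix genes at 1.89. Immediate early genes had 2.22 at E16.5 against E8.5. The 200 nuclei of E8.5 and 164 of E16.5 make this the smallest comparison, and the E8.5 class was absent under 3 other clusterings.

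Open chromatin was first compared as the sets of peaks listed by the authors for each library. Of the E8.5 peaks 39.6% overlapped a peak in both other libraries, as did 38.7% at E10.5 and 28.8% at E16.5. Promoter-proximal peaks were shared by all libraries more often, 58.8%, 56.7% and 48.9%, than distal peaks, 33.4%, 33.0% and 23.3%. Peaks listed in 1 library only were 38.1% at E8.5, 29.2% at E10.5 and 48.9% at E16.5, and 19.4%, 6.20% and 30.7% when an overlap of 1 base counted as sharing. The E16.5 list covered 172872929 bp against 106762016 and 103269550 bp, and its median peak was wider, at 669 bp against 537 and 533 bp. With an overlap of 1 base as sharing, 68.3%, 66.1% and 48.2% were in all libraries.

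Within each library, genes with high RNA in a class mostly had more open chromatin near them in that class. Of the 38 loci, 36, 27 and 29 had RNA at least 2-fold higher in their class at E8.5, E10.5 and E16.5. Promoter-proximal counts were higher in the class at 32 of 34, 27 of 27 and 27 of 28 loci, and summed distal counts at 35 of 36, 24 of 27 and 25 of 29. The median locus had a promoter ratio of 1.92, 2.33 and 2.76 and a distal ratio of 1.91, 2.12 and 2.35. The leading distal peak, chosen as the largest of many, had a median ratio of 9.24, 7.63 and 11.4.

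At Nppa the leading peak in cardiomyocyte-like nuclei was chr4:147963670-147964124 at E8.5, 36597 bp from the start and in no gene body, at 26.7-fold (14.0 to 53.0) with RNA 20.9-fold higher. At E16.5 it was a different element, chr4:147979245-147980111, 20610 bp away, at 28.9-fold (13.6 to 66.6). Myl2 had the same element inside the gene at each stage, chr5:122092524-122095057 at E8.5, at 13.4-fold, 18.6-fold and 16.3-fold. Actc1, the cardiac actin, at E10.5 led with chr2:114123254-114123754 in Aqr, 70366 bp away, at 67.1-fold (23.3 to 263). Tbx5, the atrial and left ventricular factor, had chr5:119862397-119862814 within the gene at E10.5, at 32.2-fold (11.4 to 115). Nkx2-5 had chr17:26797372-26797777, 43787 bp away, at E8.5, at 16.2-fold (8.71 to 30.8). In endothelial-like nuclei Kdr, the main receptor for vascular growth factor, had chr5:75974598-75975104 in the gene at E8.5, at 28.8-fold (15.5 to 55.2), and at E16.5 chr5:76013644-76014755, 35185 bp away, at 22.4-fold (13.5 to 38.5). Cdh5, the cadherin of endothelial junctions, had chr8:104103509-104103800 at E8.5, at 43.1-fold (17.0 to 121). Wt1, the epicardial factor, had chr2:105097412-105097734 in Wt1os at E10.5, at 15.6-fold (7.35 to 34.7). Tnni3 was an exception, its leading distal peak being at 1.13-fold (0.912 to 1.39) at E10.5 and 1.06-fold (0.920 to 1.22) at E16.5, with promoter ratios of 2.97 and 3.74.

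**Figure D4:**
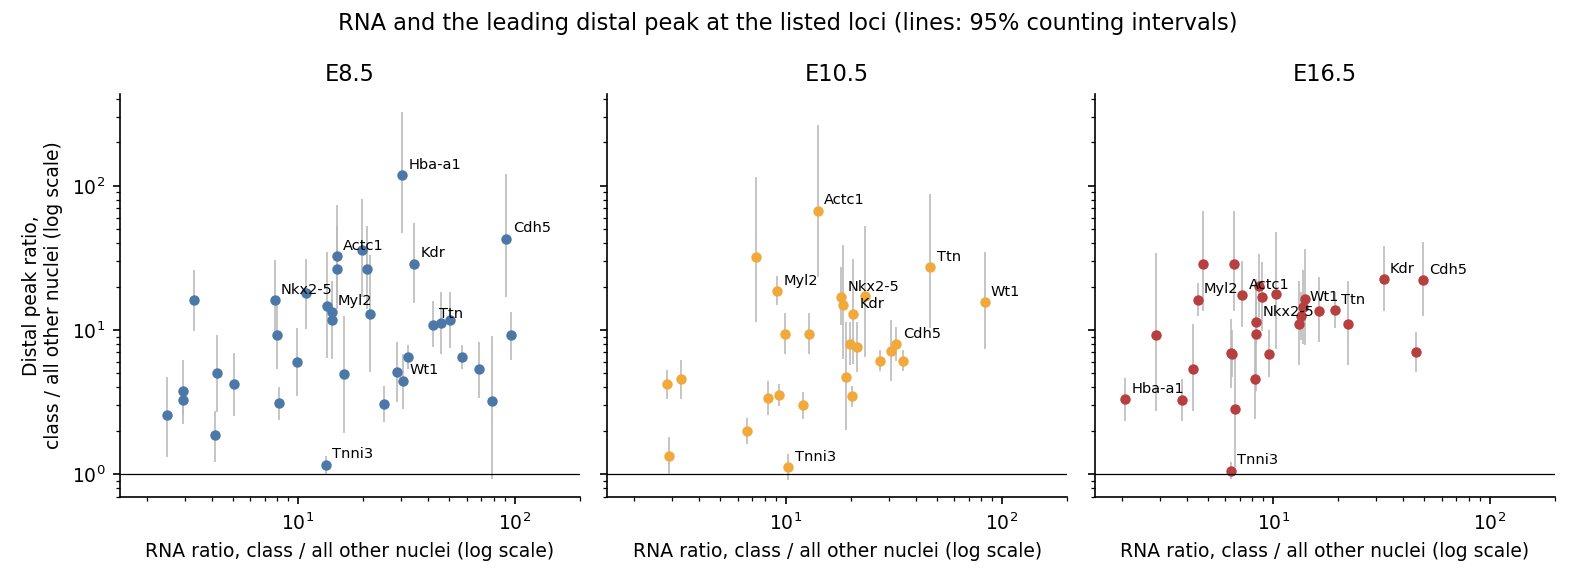
Points are loci at each stage, with the RNA ratio of the locus's class to other nuclei on the horizontal axis and the ratio of its leading distal peak on the vertical axis, both log scaled. The median leading peak ratio was 9.24, 7.63 and 11.4 at E8.5, E10.5 and E16.5.

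Across all genes the ratio of cardiomyocyte-like to endothelial-like RNA went with promoter accessibility more closely than with distal accessibility. Pearson correlations for promoters were 0.63, 0.65 and 0.70 at E8.5, E10.5 and E16.5, over 11119, 12085 and 10983 genes that are not independent replicates. For summed distal peaks they were 0.36, 0.36 and 0.43.

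Between stages, distal peaks shared by both libraries followed RNA only weakly within 1 class. Peaks listed at 1 stage only were left out, and promoter ratios were not correlated with RNA between stages. For E16.5 against E8.5, 36488 distal peaks were shared, of 88837 listed at E8.5 and 123818 at E16.5. In cardiomyocyte-like nuclei at E16.5 against E8.5, 26250 distal peaks shared by both libraries had a median log2 ratio of -0.30, while shared promoter-proximal peaks had 0.08, or -0.05 with an overlap of 1 base. Across 11151 genes the RNA ratio and the linked distal ratio had a Pearson correlation of 0.13. At Pdk4 both were higher, with chr6:5508996-5510520, 12686 bp from its start, at 42.6 and 2.64 CPM of peak counts, 16.1-fold, of which a difference in peak width can account for 2-fold, as at every such peak. Near Ndrg1, a hypoxia-responsive gene, chr15:66983883-66985652 was 13.3-fold higher in cardiomyocyte-like and 14.2-fold in endothelial-like nuclei, with RNA at 35.7 and 7.27 CPM and at 95.2 and 18.9 CPM. A peak in St7 within reach of Wnt2, chr6:17942003-17942758, was 17.5-fold lower. Within Bahcc1, a chromatin gene, chr11:120263843-120264504 was 46.5-fold lower, with RNA at 16.8 and 51.1 CPM. List values for linked peaks are medians over genes of the mean log2 ratio of each gene's peaks. For fatty acid oxidation genes this was -0.18 (percentile 78.7), inside the central range of random lists, -0.52 to -0.02. Peaks linked to cushion genes had -0.76 (percentile 0.160), to heart field genes -0.69 (percentile 1.59), to extracellular matrix genes -0.59 (percentile 1.41), whose RNA median was higher, and to heterochronic genes -0.65 (percentile 3). In endothelial-like nuclei peaks linked to coronary and capillary genes had 0.19 (percentile 98.4), which turned to -0.05 when each peak was linked to its nearest start only. Peaks linked to calcium handling and ion channel genes had a higher value there, 0.27 (percentile 99.8), and those linked to imprinted genes -0.68 (percentile 0). Peaks linked to cardiac transcription factors had -0.74 (percentile 0) there. The peak near Myadm, a membrane gene, chr7:3280066-3281550, was 14.8-fold higher in that class, with RNA at 119 and 43.4 CPM. At the imprinted Dlk1 locus chr12:109511462-109513595 was 21.9-fold lower, while Dlk1 RNA was at 46.1 and 56.2 CPM. These peak medians are not set relative to all peaks.

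Noncoding genes were used to look at transcription away from protein-coding starts, since the RNA counts are per annotated gene. Distal here means over 1 kb from every protein-coding start. These peaks lie within 500 bp of the noncoding gene's own start, so by the rule used elsewhere they are promoter-proximal. The values below therefore set a noncoding gene beside the peak at its own start. Of 4744 long noncoding genes, 1327, 1353 and 1552 started at a distal peak at E8.5, E10.5 and E16.5. Among those with enough counts, the cardiomyocyte to endothelial ratio in RNA correlated with that of the peak at the start, with Pearson coefficients of 0.57, 0.61 and 0.62 over 170, 246 and 150 genes. Genes with a 4-fold RNA ratio had their peak on the same side in 33 of 36, 61 of 72 and 40 of 46 cases. Morrbid, known from short-lived myeloid cells, was an endothelial example, 18.8-fold, 26.5-fold and 44.7-fold over cardiomyocyte-like nuclei, with its start peak at 2.45-fold, 2.24-fold and 4.85-fold. Gm13481, an unnamed locus, was a muscle example, at 93.1 CPM and 0.896 CPM at E16.5, with its peak at 14.6-fold (7.73 to 29.5). Mhrt at E8.5 was 64.0-fold higher in cardiomyocyte-like nuclei and the peak at its start 45.4-fold (8.59 to 773), though that peak lies 1394 bp from the start of Myh6. Carmn, host of smooth muscle microRNAs, differed, with RNA 20.1-fold higher in cardiomyocyte-like nuclei at E16.5 and its peak at 1.43-fold (1.07 to 1.91). Unannotated enhancer transcripts were not analysed here.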

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

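The excluded barcodes, haemoglobin and coronary values came up in a check for odd results, while the sarcomere and fatty acid oxidation patterns were weighed beside them, and both tests of the cardiomyocyte share and the scaling test of fatty acid oxidation were chosen after the result was seen. List medians in this part are not set relative to all genes.

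The first pattern is the lower share of cardiomyocyte-like nuclei at E16.5 (21.9%) than at E10.5 (40.5%), which came up because data left out of the main run held much muscle RNA. The 1114 E16.5 barcodes left out by the mitochondrial limit alone had 55801 CPM of cardiomyocyte markers (55645 to 55957), against 28464 CPM in kept nuclei, 34852 CPM in the 164 such E10.5 barcodes and 22086 CPM in the 7 at E8.5. Without that limit the shares were 36.0% and 38.3%, and with unnamed clusters led by cardiomyocyte markers added they were 38.1% and 40.5%, so both the filter and the naming rule fit as causes. The 2 overlap, since the run without the limit also kept doublets and left 18.1% of nuclei unnamed, against 30.4% in the main run. A true difference between stages stays open, because no second library exists to test it.

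The second pattern is the sarcomere list being higher in endothelial-like nuclei at E16.5 than at E8.5 (median log2 ratio 1.57). If free RNA from cardiomyocytes were the cause, members should keep 1 proportion to cardiomyocyte-like nuclei, and 63.3% of 30 were within 2-fold of a median of 8.37%, so this cannot be told apart from other causes. If free RNA of 1 profile reached every class, members should keep 1 proportion between endothelial-like and epicardial-like nuclei, and 91.7% of 24 members at E16.5 were within 2-fold of a median ratio of 1.10, which fits. The same held at E8.5 (95.8%), a value added after the result was seen, but around a median ratio of 0.516, and why the endothelial-like level differs between stages was not tested. Pairs of nuclei in 1 droplet should place the RNA in few nuclei, and the top 5% held 42.0% of marker UMIs at E16.5 against 21.1% at E8.5 and 23.1% at E10.5. Marker UMIs were in 100%, 100% and 99.9% of endothelial-like nuclei at E8.5, E10.5 and E16.5, with medians of 12, 18 and 10. Pairs are therefore not the only source of this RNA. The doublet cut called 36.8% of simulated pairs at E16.5. As causes of the higher E16.5 level, pairs and spread RNA cannot be told apart, and expression by endothelial cells stays open.

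The third pattern is fatty acid oxidation being higher in cardiomyocyte-like nuclei at E16.5 than at E8.5 (median 1.46). Gene length was not the cause by this test, the list lying at percentile 100 of random lists matched on level and length, whose central range was -0.72 to 0.08. Median-of-ratios scaling gave a median of 1.71, so the list stayed higher when the scale was set on the median gene. That scaling subtracted the same shift of -0.25 in log2 from every gene, which raised all ratios alike, and its value repeats the median relative to all genes given above. It therefore adds no separate evidence on a few genes taking a different share of UMIs. Developmental stage and any difference between the preparations are both left as possible causes, and they coincide in 1 library per stage.

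Haemoglobin genes stood out because classes differed at E16.5 against E8.5, -1.79 in cardiomyocyte-like and 1.67 in endothelial-like nuclei, a difference that was not tested and did not hold under every setting, the first turning to between 0.55 and 1.07 under 5 settings and the second to -0.0461 on thinning. Coronary and capillary genes stood out in the same way at E10.5 against E8.5, 0.60 in cardiomyocyte-like and -2.14 in endothelial-like nuclei, again untested, and the first was between -0.44 and -0.00520 under 4 other settings.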

How the results depend on the processing

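With 1 library per stage, stage and preparation coincide and no stage difference was tested. No paired analysis was possible because each library comes from its own embryos. Library depth, mitochondrial RNA and immediate early genes differ by stage, muscle marker RNA was counted in classes that are not muscle, and the number and sex of embryos are not in the labels. Where a value below differs from the main one, the cause was not tested.

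All 2016 alternative ratios of 240 named genes kept their direction, as did 1329 of 1348 alternative list medians and 147 of 150 linked distal medians. Of these values, 207, 421 and 93 kept direction but left the interval or tolerance set around the main value. The named genes had been picked for large ratios in the same counts, so their kept direction says little. Medians here are log2, not set relative to all genes.

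Shares of cardiomyocyte-like nuclei at E8.5 were 13.9% at resolution 0.5, 14.4% at resolution 2, 14.2% on peak counts, 13.9% with libraries clustered together, 15.6% with the stricter filter and 14.3% with no mitochondrial limit. At E10.5 they were 38.5% with doublets kept and 38.3% with no mitochondrial limit, and no cluster was so named with the stricter filter, which keeps 3653, 160 and 402 nuclei. At E16.5 they were 28.8% on peak counts, 2.74% with the stricter filter and 36.0% with no mitochondrial limit. Shares of endothelial-like nuclei at E10.5 were 26.1% at resolution 0.5, 23.2% with doublets kept, 16.3% with the stricter filter and 22.8% with no mitochondrial limit. At E16.5 they were 19.6% with listed genes kept in clustering, 21.2% on peak counts, 27.4% with the stricter filter and 15.9% with no mitochondrial limit.

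Thinning to 1000 UMIs gave 13 DNA replication and 3 heart field genes at least 2-fold lower in cardiomyocyte-like nuclei and 4 heterochronic genes in endothelial-like nuclei, E16.5 against E8.5. It turned these medians at E16.5 against E8.5: matrix genes in cardiomyocyte-like nuclei to -0.19, haemoglobin genes in endothelial-like to -0.0461, atrial genes in mesenchymal-like to 0.18, and in epicardial-like nuclei calcium handling to -1.19 and endocardial genes to -0.63. At E10.5 against E8.5 it turned coronary and capillary genes to -0.0869 and haemoglobin genes to -0.42 in cardiomyocyte-like nuclei, and in epicardial-like nuclei atrial genes to 0.31 and heterochronic genes to 0.14.

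Haemoglobin genes in cardiomyocyte-like nuclei at E16.5 against E8.5 turned to 0.83 with no minimum count, 0.57 with doublets kept, 1.07 on peak counts, 0.85 with libraries clustered together and 0.55 with no mitochondrial limit. In mesenchymal-like nuclei they turned to 0.50 with no minimum. Coronary and capillary genes in cardiomyocyte-like nuclei at E10.5 against E8.5 turned to -0.44 with no minimum, -0.00520 with libraries clustered together and -0.0587 with no mitochondrial limit. Calcium handling in endothelial-like nuclei at E10.5 against E8.5 turned to -0.0360 with doublets kept.

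Peaks found in every library were 68.3%, 66.1% and 48.2% at E8.5, E10.5 and E16.5 with an overlap of 1 base, by construction of the looser rule, and 52.6%, 50.1% and 38.3% in the 50% with the most counts. Linked distal medians turned for matrix genes in cardiomyocyte-like nuclei at E10.5 against E8.5, to 0.17 with an overlap of 1 base. With the nearest start only they turned in endothelial-like nuclei for coronary and capillary genes at E16.5 against E8.5, to -0.0526, and for respiratory chain genes at E16.5 against E10.5, to 0.29.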

Other observations

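Embryonic globin genes led in the early libraries. Erythroid-like nuclei at E8.5 carried Hba-x at 5754 CPM, Hbb-bh1 at 5096 CPM and Hbb-y at 4217 CPM, the embryonic globins of primitive red cells. At E10.5 Hbb-y was at 105722 CPM and Hba-x at 45068 CPM in that class. No cluster was named erythroid at E16.5, where adult Hbb-bs was instead spread at low levels over other classes. Embryonic Hbb-y was still at 117 CPM in E16.5 endothelial-like nuclei, beside Hbb-bs at 305 CPM. It was not evenly spread, being at 3.02 CPM in cardiomyocyte-like, 10.9 CPM in mesenchymal-like and 16.7 CPM in unnamed E16.5 nuclei. Its source in the endothelial-like class was not tested.

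The sex of the embryos was read from RNA. Nuclei with at least 2 Xist UMIs and none from the Y genes Ddx3y, Eif2s3y, Kdm5d and Uty were 65.9%, 40.9% and 44.6% at E8.5, E10.5 and E16.5. Nuclei with Y RNA and no Xist were 20.4%, 45.0% and 19.5%, and 31.9% at E16.5 had neither. Both kinds of nuclei were present in each library, and proportions of embryos were not estimated.

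Metabolic genes in cardiomyocyte-like nuclei did not share 1 order in time. Relative to all genes, fatty acid oxidation had a list median of 0.95 at E10.5 against E8.5 and 0.79 at E16.5 against E10.5, while glycolysis had 0.29 and -0.45. Single genes differed from their lists, Hk2 being at 617, 169 and 42.7 CPM and Ppara at 0.770, 1.47 and 35.0 CPM. Libraries at E12.5 and E14.5 with replicate embryos would give the order. Peaks linked to all fatty acid oxidation genes had a median log2 ratio of -0.18 (percentile 78.7), inside the central range of random lists, -0.52 to -0.02. The distal element 12686 bp from Pdk4 was 16.1-fold more open at E16.5, of which peak width can account for 2-fold. Deleting that element and reading Pdk4 in fetal cardiomyocytes would test whether it acts on the gene.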
